A study of Mus musculus with 12 samples.

How the data were processed

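Gene expression was measured by RNA sequencing of liver from 12 untreated adult mice, 3 of each of 4 genotypes. Per the labels' protocols, mice heterozygous for Alb/AEG-1 were crossed with mice heterozygous for Alb/c-Myc. The offspring were wild type (WT), carried the AEG-1 transgene (AEG1), carried the c-Myc transgene (MYC) or carried both (AEG1_MYC). Total RNA was taken with a Qiagen miRNeasy kit and libraries were made with an Illumina TruSeq RNA kit, per the same protocols. The labels number the mice but give no sex, age, litter, time of collection or batch. Replicate numbers were given here in accession order within each genotype and name a mouse only.

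The authors deposited 1 table of raw read counts per library, with 22609 genes and 5 summary lines. Per the submitters' processing notes, base calls came from CASAVA 1.8.2, reads were aligned with TopHat2 2.0.7 to the mouse genome build mm9, and HTSeq counted reads per gene. The HTSeq version, the gene annotation and the strand setting were not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart. The counts hold uniquely aligned reads. Alignments at several places made up 46.5% to 58.0% of all values in the tables, no-feature reads 11.5% to 15.5% of the uniquely aligned reads, and ambiguous reads 0.634% to 0.746%. The lines for low alignment quality and for unaligned reads were 0 in every library. Counts of genes with near-identical copies are uncertain for this reason, above all ribosomal proteins with their pseudogenes and the Mup, Cyp2, Cyp3a, Cyp4a, Saa, Orm and Gstm families.

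Reads in genes came to 21931197 to 40552316 per library, and 15496 to 16464 genes had at least 1 read. Summary lines stayed out of library sizes and tests. Of the 22609 genes, 4439 had 0 counts in all 12 libraries and 13684 passed edgeR's filterByExpr and were tested. The median SE of a log2 fold change was 0.208 for a comparison of 3 against 3 mice and 0.294 for the interaction.

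Counts were analysed in R 4.3.3 with edgeR 4.0.16. Library sizes were scaled by TMM (factors 0.914 to 1.19), 1 coefficient was fitted per genotype over all 12 libraries with a shared dispersion trend, and genes were tested with the robust quasi-likelihood F test, two-sided. Adjusted p values are Benjamini-Hochberg values over the 13684 genes, and a gene was called at an adjusted p under 0.05. SEs are the size of the log2 fold change divided by the square root of F. The 6 contrasts were AEG1, MYC and AEG1_MYC each against WT, AEG1_MYC against AEG1, AEG1_MYC against MYC, and the interaction of the 2 transgenes, which is (AEG1_MYC minus MYC) minus (AEG1 minus WT) on the log2 scale. CPM values (read counts scaled to a common library total) were computed over TMM-scaled library sizes.

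Gene groups were tested as 40 lists of liver functions, hepatic zones, sex-biased genes, signalling responses and markers of other cell types. Some genes stand in more than 1 list, such as Aldh1b1 in both the pericentral and the periportal list. Each list was tested in each of the 6 contrasts with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the 240 tests. Camera compares a list with all other genes. An estimated correlation and fry, which tests whether a list's genes move one way on balance, were the alternatives. With an estimated correlation 0 of the 81 called tests held, and fry called 10 of the 240 tests. By mistake the camera test was first run on edgeR's z-scores of the counts, so those values (88 calls) were seen before the log2 CPM test fixed in the design (81 calls) was run. It is kept as an alternative.

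The groups, contrasts, tests, gene lists, most alternatives and the rule for named genes were fixed before the data were examined. For contrasts against WT the rule takes the 10 largest rises and the 10 largest falls among called genes with a mean CPM of at least 1 over the libraries compared and with no overlap between the groups. For the other contrasts it takes 5 and 5, for the interaction with the CPM limit over all 12 libraries. It adds up to 4 called members of each list by p, and Myc and Mtdh always. Genes named outside this rule were chosen after their values were seen. Some genes the rule gives are not reported here.

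The alternatives were RLE and upper-quartile scaling, no filter on low counts, a filter of CPM of at least 1 in at least 3 libraries, no robust step, DESeq2 1.42.0, limma with library quality weights, 1 surrogate variable from sva 3.50.0, the 6 compared libraries alone, and leaving out each library in turn. A sex covariate was planned for the case that both sexes occurred, and was not run. Chosen after the data were seen were a clock score as a covariate, the 9 libraries without AEG1_MYC, and leaving out AEG1_MYC replicates 1 and 2 together. That last setting leaves AEG1_MYC replicate 3 as the 1 library of its group, which is then assumed to vary like the other groups. The clock score is the first principal component of the circadian list (84.2% of its variance). DESeq2 was given 18170 genes, and adjusted p values it left as NA stayed NA.

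The fit was tested on simulated counts for MYC versus WT over 13684 genes. With the spread of all 12 libraries, 46 of 100 genes changed 2-fold and 90 of 100 genes changed 4-fold were called, along with 6 unchanged genes. With the spread of the 9 libraries without AEG1_MYC the values were 65, 94 and 4. A list shifted 1.5-fold was called and 0 other lists were. The simulated genes were drawn independently of each other, so this does not test list calls among correlated genes. No pair of libraries within a genotype agreed within sampling noise, the lowest chi-square per degree of freedom being 35.8 over 12 pairs.

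Gene symbols are those of the count tables. Chromosome membership and gene order came from a RefSeq gene table of GRCm38.p6, which is not the authors' build. It was used for names and neighbours, matched 13599 of the 13684 tested symbols (99.4%), and no coordinates are given.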

Results

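Liver RNA was sequenced from 12 untreated adult mice, 3 each of WT, AEG1, MYC and AEG1_MYC genotype. AEG-1, astrocyte elevated gene-1, is the protein of Mtdh, and c-Myc is a transcription factor of growth and proliferation. Both transgenes are of Alb lines, in which the albumin promoter drives expression in hepatocytes. The series is about how AEG-1 and c-Myc act together in the formation of liver tumours. Each library held 21931197 (AEG1 replicate 2) to 40552316 (AEG1 replicate 3) reads in genes. Values below are mean CPM ± SD over 3 mice or log2 fold changes ± SE, and adjusted p values are edgeR's for genes and camera's for lists.

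Myc stood at 3.26 ± 1.3 CPM in WT and 4.02 ± 0.532 in AEG1 livers, 35.9 ± 15.9 in MYC and 98.8 ± 57.9 in AEG1_MYC livers. Every MYC and AEG1_MYC library (23.4 to 165 CPM) lay above every WT and AEG1 library (2.26 to 4.73 CPM). Myc rose in AEG1_MYC against WT (4.91 ± 0.50, adjusted p = 0.00345) and against AEG1 (4.61 ± 0.49, adjusted p = 0.00523). The difference of 3.45 ± 0.47 between MYC and WT did not pass over all genes (adjusted p = 0.266), nor did that of 1.46 ± 0.42 between AEG1_MYC and MYC (adjusted p = 0.200) or the 0.30 ± 0.45 between AEG1 and WT. Without AEG1_MYC replicate 2, Myc was called in MYC versus WT (adjusted p = 0.0410). Mtdh was 100.3 ± 1.11 CPM in WT, 97.4 ± 4.04 in AEG1, 97.2 ± 1.93 in MYC and 97.6 ± 12.9 in AEG1_MYC livers. Its log2 fold changes against WT were -0.04, -0.05 and -0.04, each ± 0.10, with adjusted p values of 0.9997, 0.999 and 0.858. The labels do not say from which species the AEG-1 transgene comes, and reads of a transgene from another species may not be counted at mouse Mtdh, so Mtdh does not check the AEG1 label.

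AEG1_MYC replicates 1 and 2 lay apart from the rest and from each other, and replicate 3 lay near the other genotypes. The first principal component (36.0% of the variance) placed AEG1_MYC replicate 2 at 99.2, replicate 1 at 34.1 and replicate 3 at 10.7. The mean correlation of log2 CPM with the other libraries was 0.923 for AEG1_MYC replicate 2 and 0.955 for replicate 1. For the rest it was 0.968 to 0.972, with AEG1_MYC replicate 3 at 0.970. That library correlated more with WT replicate 3 (0.981) than with AEG1_MYC replicate 1 (0.965) or 2 (0.940). In AEG1_MYC replicate 2 the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were at 2.51% to 5.70% of their mean in the other 11 libraries, while Xist was 0.533 CPM there and at most 0.781 CPM elsewhere. Replicate 2 also held Glul, glutamine synthetase of pericentral hepatocytes, at 15863 CPM against 3064 and 3071 in replicates 1 and 3, and the periportal Cyp2f2 at 2.70 CPM against 508 and 1039. AEG1_MYC replicate 1 held the acute-phase gene Saa1 at 3331 CPM, against 4.30 to 45.0 CPM in the other 11 libraries. Albumin took 9.02% of reads in WT replicate 1, the highest share, and 2.87% in AEG1_MYC replicate 2, the lowest. The clock score ran from -8.76 to 7.56 and was 3.91 to 7.29 in the 3 AEG1_MYC libraries, above WT at -5.14 to 3.01.

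**Figure D1:**
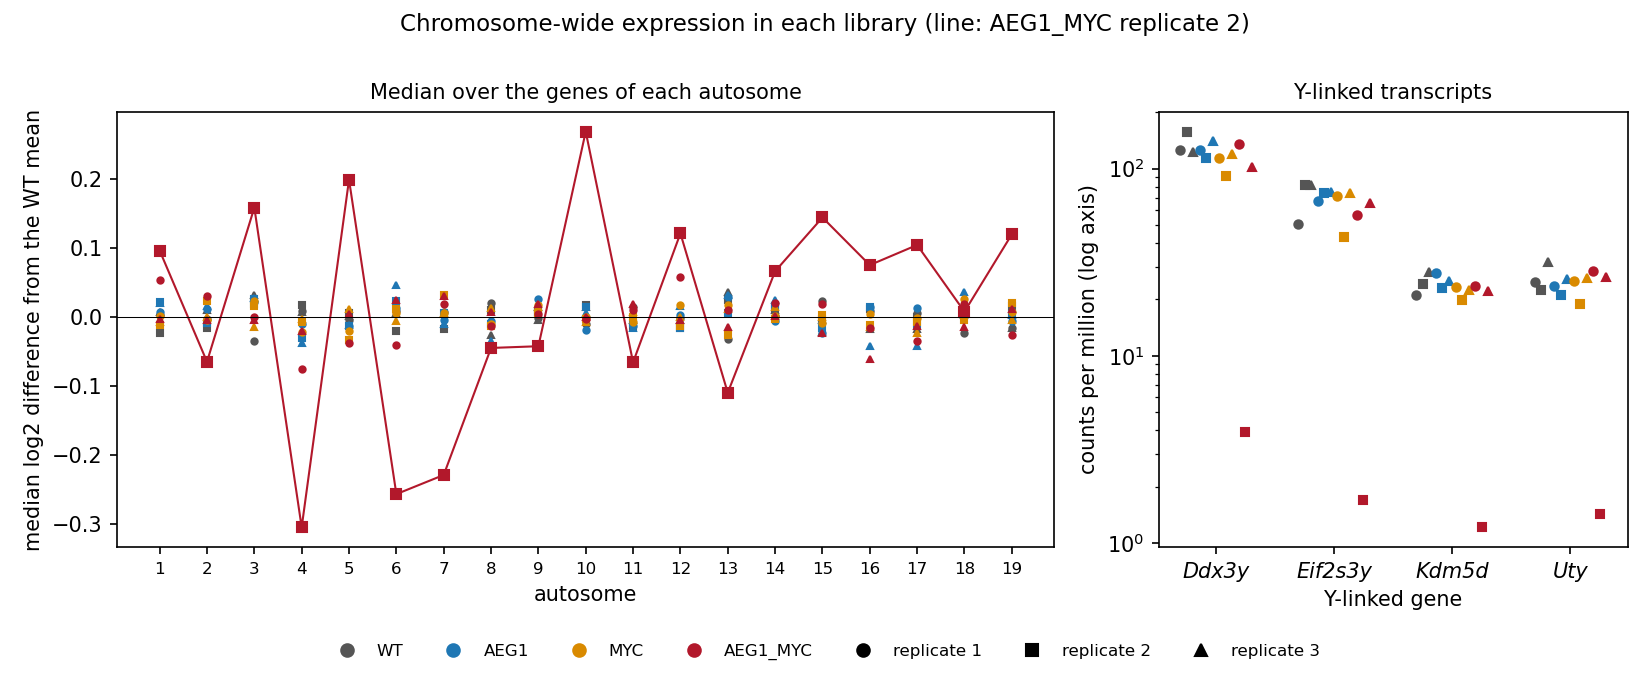
Left, the median log2 difference from the WT mean of each autosome (horizontal axis) for each of the 12 libraries, with a line through AEG1_MYC replicate 2, whose lowest value is -0.31 on chromosome 4. Right, CPM on a log axis of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty in each library, with AEG1_MYC replicate 2 at 2.51% to 5.70% of the mean of the other 11.

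AEG1 against WT asked what the AEG-1 transgene did alone. Interferon-response genes were lower as a group in AEG1 livers, with negative fold changes in 29 of 31 members and a median of -0.69 (adjusted p = 2.3e-10, and adjusted p = 0.708 with an estimated correlation). Irf9, a transcription factor of interferon signalling, stood at -0.58 ± 0.18 and the interferon-induced GTPase Gbp6 at -1.15 ± 0.40 (3 mice against 3). Genes of lipogenesis were higher as a group, 21 of 25 with a median of 0.53 (adjusted p = 7.5e-05, and adjusted p = 0.708 with an estimated correlation), among them the fatty acid elongase Elovl6 at 1.57 ± 0.39 and fatty acid synthase, Fasn, at 0.70 ± 0.36. Endothelial markers were higher as a group, 15 of 15 with a median of 0.31 (adjusted p = 3.4e-06, and adjusted p = 0.486 with an estimated correlation), with the VEGF receptor Kdr at 0.43 ± 0.13. Pericentral hepatocyte genes were lower as a group, 20 of 22 with a median of -0.34 (adjusted p = 3.5e-04, and adjusted p = 0.763 with an estimated correlation), including the Wnt targets Notum at -0.71 ± 0.36 and Sp5 at -0.95 ± 0.52. None of these genes passed on its own. In edgeR 0 of 13684 genes were called (lowest adjusted p = 0.836) and 536 had an unadjusted p under 0.05, where 684 would be so by chance. DESeq2 called 15, 8 up and 7 down, and limma 0. The groups did not overlap in 1463 genes, 10.7%, where chance gives 10%.

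Camera called 9 lists in AEG1 versus WT, interferon response, endothelial markers, lipogenesis and pericentral genes among them. Fry called 0 lists in this comparison. Angiogenesis genes had a median of 0.17 (19 of 23 positive, adjusted p = 9.0e-04, and adjusted p = 0.571 with an estimated correlation), with the VEGF receptors Flt1 at 0.33 ± 0.10 and Flt4 at 0.52 ± 0.19. Hepatocyte secretory proteins had a median of -0.18 (19 of 24 negative, adjusted p = 0.0102, and adjusted p = 0.770 with an estimated correlation), with Ahsg at -0.43 ± 0.14. Coagulation genes had a median of -0.11 (22 of 24 negative, adjusted p = 0.0134, and adjusted p = 0.770 with an estimated correlation). B and plasma cell markers had a median of 0.69 (10 of 10 positive, adjusted p = 0.0189, and adjusted p = 0.842 with an estimated correlation), with the B cell receptor subunit Cd79a at 1.01 ± 0.60. Genes biased to female mouse liver had a median of 0.32 (12 of 18 positive, adjusted p = 0.0257, and adjusted p = 0.571 with an estimated correlation). Adjusted over the list alone, Elovl6 in lipogenesis and 1 female-biased gene were called up, and 0 members of the other 7 lists; over all genes the counts were 0.

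Some of these calls were lost without single libraries. Without AEG1 replicate 3 the calls of secretory proteins, coagulation, lipogenesis, female-biased genes and B cell markers were lost (adjusted p = 0.211, 0.158, 0.109, 0.178 and 0.812), the last with a median of -0.03. The female-biased call was also lost without WT replicate 1 (adjusted p = 0.105) or AEG1 replicate 2 (0.0771), the pericentral call without WT replicate 1 (0.103), the secretory call without WT replicate 2 (0.0866) and the B cell call without WT replicate 3 (0.256). Where calls were lost without AEG1 replicate 3, medians were -0.08 for secretory proteins, 0.29 for lipogenesis and 0.06 for female-biased genes. That of coagulation hardly moved, at -0.10 against -0.11 with all libraries. Lost calls without WT replicate 1 had medians of -0.10 for pericentral and 0.54 for female-biased genes. Secretory proteins had -0.16 without WT replicate 2 and B cell markers 0.54 without WT replicate 3. With the call kept, the median moved by over 1.5 times for angiogenesis (0.26 without WT replicate 1, 0.27 without AEG1 replicate 1), female-biased genes (0.60 without WT replicate 2, 0.54 without AEG1 replicate 1) and endothelial markers (0.20 without AEG1 replicate 3).

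MYC against WT asked what the c-Myc transgene did alone. Cytosolic ribosomal proteins were higher as a group in MYC livers, 45 of 46 with a median of 0.49 (adjusted p = 2.4e-31, and adjusted p = 0.486 with an estimated correlation), among them Rps19 at 0.86 ± 0.20 and Rpl32 at 0.61 ± 0.12. Ribosome biogenesis genes had a median of 0.17 (39 of 44 positive, adjusted p = 5.1e-04, and adjusted p = 0.855 with an estimated correlation), with the nucleolar proteins Nhp2 at 0.75 ± 0.18 and Npm1 at 0.40 ± 0.16. Cell cycle genes had a median of 0.24 (27 of 39 positive, adjusted p = 0.00167, and adjusted p = 0.855 with an estimated correlation), with cyclin E1, Ccne1, at 2.19 ± 0.65, E2f1 at 0.69 ± 0.21 and cyclin D1, Ccnd1, at -1.35 ± 0.50. Pericentral genes were lower as a group (20 of 22, median -0.42, adjusted p = 1.6e-06, and adjusted p = 0.708 with an estimated correlation), with Cyp7a1, the rate-limiting enzyme of bile acid synthesis, at -1.18 ± 0.37 and Nkd1, an inhibitor and target of Wnt signalling, at -0.41 ± 0.15. Cholesterol synthesis genes were lower as a group (22 of 24, median -0.35, adjusted p = 1.0e-06, and adjusted p = 0.708 with an estimated correlation), with squalene epoxidase, Sqle, at -0.87 ± 0.39. No gene passed on its own: edgeR called 0 of 13684 (lowest adjusted p = 0.266, Myc) and 475 had an unadjusted p under 0.05. DESeq2 called 28, 19 up and 9 down, and limma 0. Groups did not overlap in 1582 genes, 11.6%, where chance gives 10%. With the clock score as a covariate Gtf2ird1, named after its value was seen, was called (-1.14, adjusted p = 0.0254).

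Camera called 14 lists in MYC versus WT, those of ribosomal proteins, ribosome biogenesis, cell cycle, pericentral genes and cholesterol synthesis among them. Fry called 0 lists here, ribosomal proteins included. Coagulation genes were lower as a group (23 of 24, median -0.22, adjusted p = 8.2e-06, and adjusted p = 0.690 with an estimated correlation), as were bile acid genes (21 of 23, median -0.27, adjusted p = 8.0e-05, and adjusted p = 0.486 with an estimated correlation). Secretory proteins had a median of -0.16 (22 of 24 negative, adjusted p = 1.4e-04, and adjusted p = 0.708 with an estimated correlation). Urea cycle and amino acid breakdown had a median of -0.16 (23 of 32 negative, adjusted p = 0.0137, and adjusted p = 0.855 with an estimated correlation), with the tyrosine-degrading enzyme Hpd at -0.48 ± 0.16. Fetal liver and liver tumour genes had a median of 0.30 (24 of 25 positive, adjusted p = 0.00306, and adjusted p = 0.695 with an estimated correlation), with the duct keratin Krt7 at 1.19 ± 0.50. Imprinted and long noncoding transcripts had a median of 0.26 (15 of 18 positive, adjusted p = 0.0101, and adjusted p = 0.690 with an estimated correlation). Nucleotide, serine and one-carbon synthesis had a median of 0.11 (adjusted p = 0.0387), p53 response genes 0.18 (0.0471) and bile duct markers 0.43 (0.0491), each with adjusted p = 0.708 with an estimated correlation. Adjusted over the list alone, 21 ribosomal proteins and the snoRNA host Gas5 (0.71 ± 0.11) were called up, and 0 members of the other 12 lists; over all genes the counts were 0.

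The weaker of these calls were lost without single libraries, some of them AEG1 or AEG1_MYC libraries outside this comparison. Medians of calls lost without the latter were 0.42 to 0.44 for bile duct, 0.16 to 0.17 for p53 and 0.12 for nucleotide genes. With all libraries they were 0.43, 0.18 and 0.11. The bile duct call was lost without WT replicate 1 or 2, AEG1 replicate 2 or 3, MYC replicate 1 or 3, or AEG1_MYC replicate 1, 2 or 3 (adjusted p = 0.0531 to 0.540). The p53 call was lost without WT replicate 2, any AEG1 replicate, MYC replicate 2 or 3, or AEG1_MYC replicate 1 or 3 (0.0589 to 0.536). The nucleotide call was lost without WT replicate 2 or 3, AEG1 replicate 3, MYC replicate 2 or 3, or AEG1_MYC replicate 1 (0.0504 to 0.333). The fetal (0.0626), imprinted (0.163) and ribosome biogenesis (0.656) calls were lost without MYC replicate 3. The cell cycle call was lost without MYC replicate 2 (0.185) and the urea cycle call without MYC replicate 1 (0.0532, median -0.12). Leaving out WT replicate 1 ended the imprinted call (0.302), with the median at 0.25. The cell cycle call ended without WT replicate 2 (0.551), and the ribosome biogenesis and urea cycle calls without WT replicate 3 (0.280 and 0.417). The urea cycle median turned from -0.16 to 0.01 there, and the ribosome biogenesis median was 0.06. Without MYC replicate 3 medians were 0.03 for ribosome biogenesis, 0.16 for fetal, 0.17 for imprinted, 0.02 for nucleotide synthesis and 0.08 for bile duct genes. Without MYC replicate 2 they were 0.07 for cell cycle, 0.05 for nucleotide synthesis and 0.08 for p53 genes. Cell cycle and p53 genes had 0.02 and 0.06 without WT replicate 2, and bile duct markers 0.10 without WT replicate 1. Among kept calls, the cell cycle median was 0.64 without WT replicate 1 and 0.16 without WT replicate 3, and the pericentral median -0.21 without WT replicate 1 and -0.63 without MYC replicate 2. Ribosome biogenesis had a median of 0.29 without WT replicate 2 and 0.27 without MYC replicate 1, and the fetal list 0.46 without WT replicate 3 and 0.48 without MYC replicate 1. Nucleotide synthesis had 0.17 without WT replicate 1 and 0.19 without MYC replicate 1, and bile duct markers had 0.79 without WT replicate 3.

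AEG1_MYC against WT asked what both transgenes did together. Nkd1 rose from 6.18 ± 0.841 to 70.0 ± 12.5 CPM (3.50 ± 0.16, adjusted p = 3.4e-06), and the pancreatic lipase relative Pnliprp1 from 0.0912 ± 0.0529 to 17.7 ± 7.53 CPM (7.61 ± 0.56, adjusted p = 2.9e-04). Of the noncoding RNAs of the imprinted Dlk1 region, Rian rose from 1.47 ± 0.856 to 89.2 ± 31.2 CPM (5.95 ± 0.61, adjusted p = 0.00345) and Meg3 from 5.43 ± 4.18 to 281 ± 64.4 CPM (5.71 ± 0.85, adjusted p = 0.0304). The pericentral transporters rose: Rhbg, which carries ammonium, from 13.4 ± 1.28 to 138 ± 89.2 CPM (3.37 ± 0.44, adjusted p = 0.0156) and Slc1a2, which carries glutamate, from 185 ± 102 to 1406 ± 798 CPM (2.93 ± 0.45, adjusted p = 0.0334). The export pump Abcc4 rose from 2.27 ± 0.286 to 45.6 ± 26.99 CPM (4.33 ± 0.51, adjusted p = 0.00869).

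**Figure D2:**
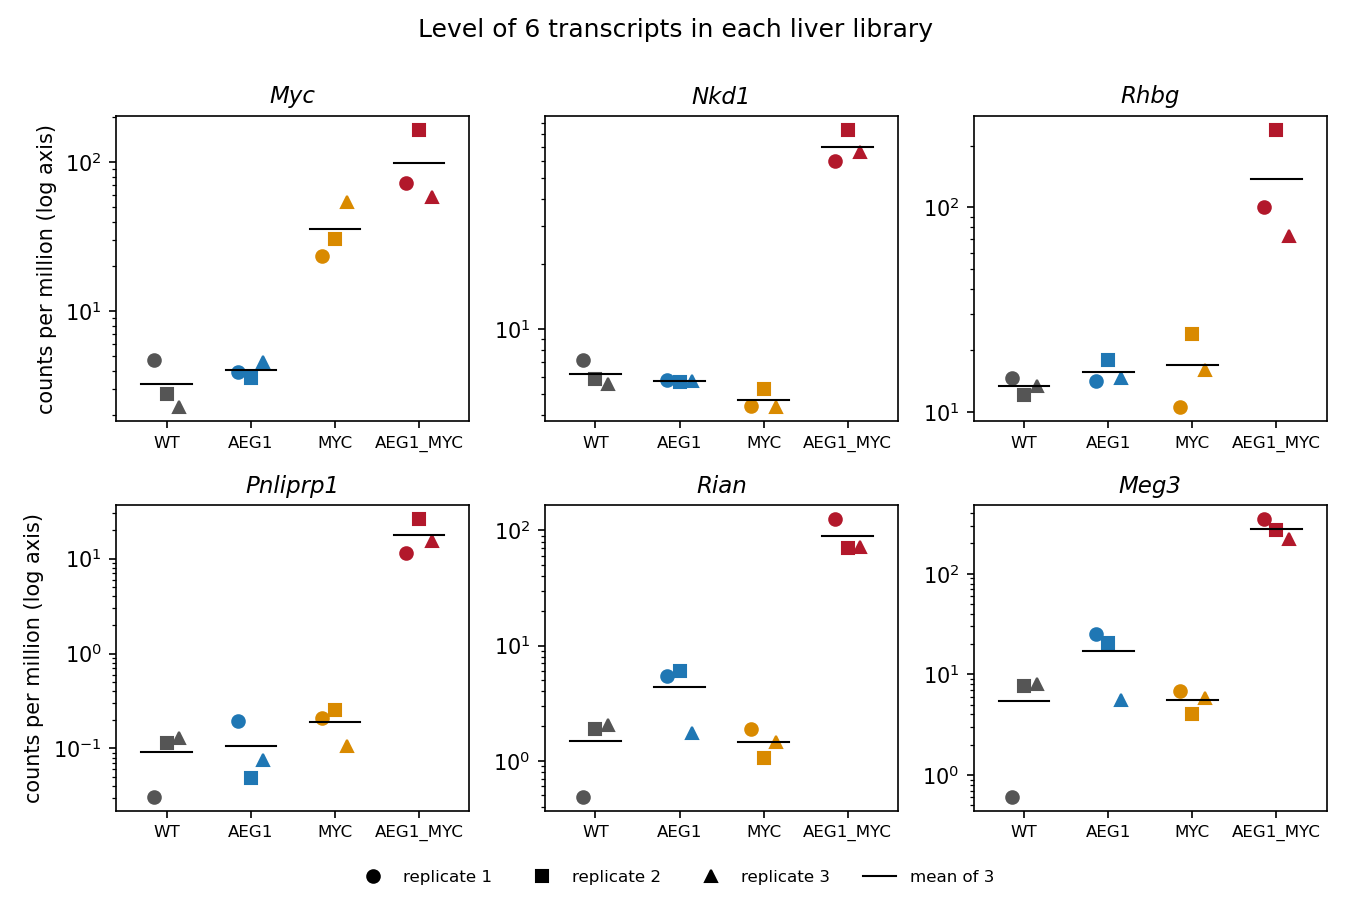
CPM on a log axis of Myc, Nkd1, Rhbg, Pnliprp1, Rian and Meg3 in each of the 12 libraries by genotype, with 1 marker shape per replicate number and a horizontal line at the mean of 3. Nkd1 lies at 59.9 to 83.9 CPM in AEG1_MYC and at 4.32 to 7.14 CPM in the other 9 libraries.

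In all 36 genes were called in AEG1_MYC versus WT, 35 up and 1 down, 34 of them with a log2 fold change of at least 1 in size. The urate transporter Slc22a12 had the largest rise the rule named (8.47 ± 1.29, adjusted p = 0.0334), at 32.7, 47.2 and 1.67 CPM in the 3 AEG1_MYC livers and 6 reads in all of WT. Besides Pnliprp1, Rian, Meg3 and Myc, given above, the largest rises reported were those of the tubulin Tuba8 (5.97 ± 1.01, adjusted p = 0.0475), AF357359 (5.77 ± 0.75, adjusted p = 0.0156), the acyltransferase Mogat2 (5.73 ± 0.94, adjusted p = 0.0461) and Mirg, a further noncoding RNA of the Dlk1 region (5.20 ± 0.80, adjusted p = 0.0334). No fall met the rule; the fall called was that of Gm13251 (-2.10 ± 0.33, adjusted p = 0.0354), named after its value was seen. At an unadjusted p under 0.05 were 2356 genes, and groups did not overlap in 2663, 19.5%, where chance gives 10%. DESeq2 called 653 genes, all 36 among them, 458 up and 195 down, and limma 23. The count was 9 with a surrogate variable, 12 with the clock score, 2 (Nkd1 and Pnliprp1) with the 6 compared libraries alone and 4 (Gm106, Myc, Nkd1 and Pnliprp1) without AEG1_MYC replicates 1 and 2. In that fit replicate 3 is the 1 library of its group and is assumed to vary like the other groups.

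That count moved with single libraries. It was 10, 6 and 8 without WT replicate 1, 2 or 3, 18, 13 and 23 without AEG1 replicate 1, 2 or 3, and 13, 12 and 16 without MYC replicate 1, 2 or 3. It was 18 without AEG1_MYC replicate 2 and 687 without AEG1_MYC replicate 3, with all 36 among the latter. Nkd1, Pnliprp1, Myc and Rian kept their calls in 12 of 12 such fits, with adjusted p values of at most 1.5e-04, 0.00595, 0.0473 and 0.0426. AF357359 kept it in 10, Abcc4 and Rhbg in 9, Meg3 and Mirg in 4, Slc1a2 in 3, and Slc22a12, Tuba8 and Mogat2 in 1, the fit without AEG1_MYC replicate 3.

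Genes of the hepatic zones differed between AEG1_MYC and WT. Pericentral genes were higher as a group, 21 of 22 with a median of 1.03 (adjusted p = 2.3e-11, and adjusted p = 0.690 with an estimated correlation), with Glul at 2.95 ± 0.65, the Wnt target Sp5 at 2.48 ± 0.51 and ornithine aminotransferase, Oat, at 1.75 ± 0.43. Called members over all genes were Nkd1, Rhbg and Slc1a2, and 16 passed adjusted over the list alone. Periportal genes were lower as a group, 18 of 20 with a median of -0.65 (adjusted p = 5.8e-04, and adjusted p = 0.837 with an estimated correlation). Without AEG1_MYC replicate 2 that median was -0.09 and the call was lost (adjusted p = 0.384). Without WT replicate 3 it was -0.39. The pericentral median was 0.65 without AEG1_MYC replicate 2, with the call kept (adjusted p = 4.8e-10). Fry called the pericentral list (adjusted p = 0.0259), the imprinted list (adjusted p = 0.0110) and the pancreatic acinar list of 2 tested genes (adjusted p = 0.00684), the last not called by camera (adjusted p = 0.178).

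Cell cycle genes were higher as a group, 37 of 39 with a median of 1.19 (adjusted p = 1.9e-12, and adjusted p = 0.690 with an estimated correlation), with topoisomerase Top2a at 2.08 ± 0.52 and the mitotic kinases Cdk1 at 2.01 ± 0.61 and Bub1 at 2.64 ± 0.68. Ribosomal proteins had a median of 0.54 (41 of 46 positive, adjusted p = 5.2e-14, and adjusted p = 0.690 with an estimated correlation) and ribosome biogenesis genes 0.23 (36 of 44, adjusted p = 0.00625, and adjusted p = 0.855 with an estimated correlation). Imprinted and long noncoding transcripts had a median of 0.48 (15 of 18 positive, adjusted p = 7.9e-06, and adjusted p = 0.486 with an estimated correlation), with Airn at 2.34 ± 0.63 and Snhg1 at 1.04 ± 0.28 besides the called Rian, Meg3 and Mirg. Fetal liver and liver tumour genes had a median of 0.43 (15 of 25 positive, adjusted p = 0.0403, and adjusted p = 0.708 with an estimated correlation), with Ly6d at 2.79 ± 0.74 and Anxa2 at 1.85 ± 0.46. Nucleotide and one-carbon synthesis had a median of 0.26 (23 of 31 positive, adjusted p = 0.0318, and adjusted p = 0.708 with an estimated correlation), with the amino acid transporter Slc7a5 at 1.70 ± 0.36. NRF2 targets had a median of 0.26 (15 of 24 positive, adjusted p = 0.0232, and adjusted p = 0.763 with an estimated correlation), with the called Abcc4, the glutathione transferase Gstm3 at 3.30 ± 0.71 and the quinone reductase Nqo1 at 1.81 ± 0.54. Acute phase genes had a median of 0.86 (26 of 31 positive, adjusted p = 0.00935, and adjusted p = 0.855 with an estimated correlation) with all libraries, and 0.04 without AEG1_MYC replicate 1 (adjusted p = 0.934). In that library the mean log2 difference from WT was 2.19 for acute phase genes, 4.33 for neutrophil markers (-1.29 to 1.68 in the other 11 libraries) and 1.59 for Kupffer cell and macrophage markers (at most 0.89 in the others).

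Lower as groups were unfolded protein response genes (22 of 26, median -0.55, adjusted p = 1.6e-04, and adjusted p = 0.708 with an estimated correlation), with the chaperones Hspa5 at -1.03 ± 0.34 and Hyou1 at -1.42 ± 0.45 and, the other way, Atf3 at 1.41 ± 0.42. Cholesterol synthesis genes were lower (22 of 24, median -0.45, adjusted p = 9.1e-06, and adjusted p = 0.708 with an estimated correlation), with Mvd at -1.15 ± 0.31 and Lss at -0.74 ± 0.24. Genes biased to male mouse liver were lower (21 of 22, median -0.67, adjusted p = 3.4e-05, and adjusted p = 0.708 with an estimated correlation), with the elongase Elovl3 at -3.23 ± 0.92, and female-biased genes higher (16 of 18, median 0.69, adjusted p = 0.0387, and adjusted p = 0.684 with an estimated correlation), with Fmo2 at 1.98 ± 0.58. The mean log2 difference of male-biased genes from WT was -1.15, -3.02 and -0.10 in AEG1_MYC replicates 1, 2 and 3, against -0.44 to 0.42 in WT libraries. With replicate 3 as the 1 AEG1_MYC library the call was lost (median -0.15, adjusted p = 0.666). Coagulation genes had a median of -0.27 (adjusted p = 1.0e-04, and adjusted p = 0.695 with an estimated correlation), with the plasmin inhibitor Serpinf2 at -0.77 ± 0.20. Secretory proteins had a median of -0.17 (adjusted p = 0.00140, and adjusted p = 0.708 with an estimated correlation), with Alb at -1.13 ± 0.28. Interferon-response genes had a median of -0.41 (28 of 31 negative, adjusted p = 0.00214, and adjusted p = 0.855 with an estimated correlation). Adjusted over the list alone, 30 ribosomal proteins, 17 cell cycle, 9 fetal, 8 NRF2, 7 imprinted, 5 acute phase, 2 nucleotide and 1 unfolded protein response gene were called up. Called down in this way were 9 unfolded protein response, 8 cholesterol, 2 secretory, 1 NRF2 and 1 nucleotide gene, and 0 members of the 6 remaining lists. Over all genes 3 pericentral, 3 imprinted and 1 NRF2 gene were called.

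Of these 17 calls, that of the fetal list was lost without WT replicate 1 or 2, AEG1 replicate 2 or 3, any MYC replicate, or AEG1_MYC replicate 1 (adjusted p = 0.0529 to 0.141). In all of these fits but the last its median stayed at 0.41 to 0.44, with 0.43 in all libraries. The female-biased call was lost without WT replicate 1, MYC replicate 1 or any AEG1_MYC replicate (0.0543 to 0.110), and the nucleotide call without WT replicate 3 or AEG1_MYC replicate 1 or 2 (0.0637 to 0.0932). NRF2 was lost without WT replicate 1 (0.107) or AEG1 replicate 3 (0.0510). Leaving out WT replicate 3 ended the acute phase (0.0731), interferon (0.147) and ribosome biogenesis (0.258) calls. The interferon (0.0568) and ribosome biogenesis (0.251) calls were also lost without AEG1_MYC replicate 2. Where calls were lost without WT replicate 3, medians were -0.15 for interferon, 0.11 for ribosome biogenesis and 0.75 for acute phase genes (0.86 with all libraries). For female-biased genes the median was 1.10 without WT replicate 1 and 0.59 to 0.73 in the other fits that lost the call. Lost calls had medians of 0.21 for the fetal list without AEG1_MYC replicate 1, and 0.11 for ribosome biogenesis and 0.12 for nucleotide genes without replicate 2. With the call kept, the cell cycle median was 0.77, coagulation -0.17, secretory proteins -0.08 and NRF2 0.07 without AEG1_MYC replicate 2, and secretory proteins -0.41 and cholesterol synthesis -0.27 without replicate 1. Without replicate 3 it was 0.38 for ribosome biogenesis, -0.74 for interferon response and -1.34 for male-biased genes, the last -1.03 without WT replicate 1. Ribosome biogenesis was 0.39 without WT replicate 2, the fetal list 0.66 without WT replicate 3, and female-biased genes 1.12 and 1.63 without WT replicate 2 or 3. With replicate 3 as the 1 AEG1_MYC library, assumed to vary like the other groups, 8 of the 17 lists were called. Medians were then 0.64 for pericentral, 0.64 for cell cycle, 0.41 for ribosomal protein, 0.10 for imprinted, -0.36 for unfolded protein response, -0.38 for cholesterol, -0.11 for coagulation and -0.21 for secretory genes.

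**Figure D3:**
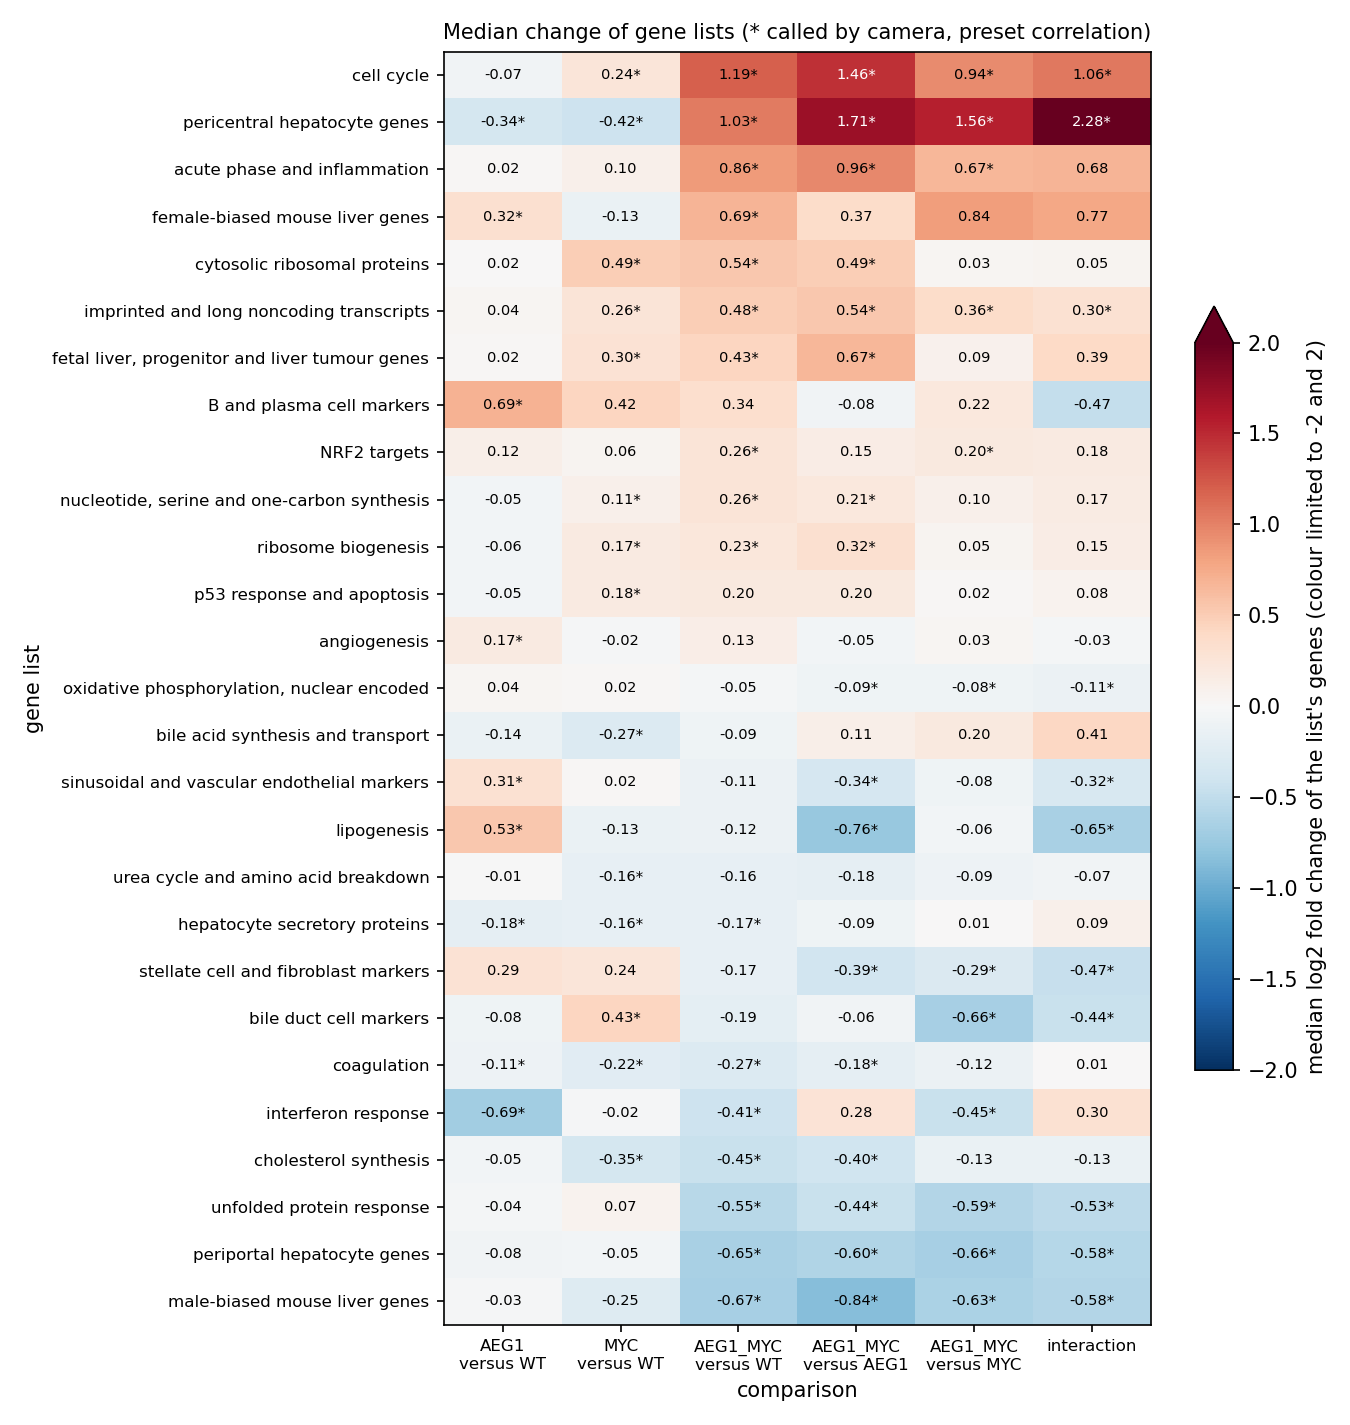
Median log2 fold change (colour, limited to -2 and 2) of the 27 gene lists with more than 2 tested genes that camera called in at least 1 of the 6 comparisons, with lists as lines and comparisons as columns. A star marks a call with the preset correlation; the pericentral list runs from -0.42 in MYC versus WT to 2.28 in the interaction.

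AEG1_MYC against AEG1 asked what c-Myc added to AEG-1. Nkd1 rose by 3.61 ± 0.16 (adjusted p = 2.6e-06) and Pnliprp1 by 7.25 ± 0.54 (adjusted p = 3.1e-04), and the largest rise was again that of Slc22a12 (9.24 ± 1.36). The kinesin Kif26b (4.91 ± 0.71, adjusted p = 0.0213) and AF357359 (4.69 ± 0.68) rose too. Aacs, an enzyme that activates acetoacetate for lipid synthesis, fell by 1.46 ± 0.25 (adjusted p = 0.0458) from 338 ± 54.7 to 123 ± 41.1 CPM, with 146 ± 2.52 in WT, and Gucy1b3, a subunit of soluble guanylate cyclase, fell by 1.26 ± 0.22 (adjusted p = 0.0473). Rian rose by 4.36 ± 0.56 (adjusted p = 0.0142), while Meg3 at 4.05 ± 0.78 was not called (adjusted p = 0.0724). The cytokine-signalling inhibitor Socs3 rose by 1.795 ± 0.299 (adjusted p = 0.0409) and the bile acid racemase Amacr by 0.80 ± 0.14 (adjusted p = 0.0458). In all 44 genes were called, 41 up and 3 down, with 2387 at an unadjusted p under 0.05 and no overlap in 2441 genes, 17.8%, where chance gives 10%.

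DESeq2 called 712 genes in AEG1_MYC versus AEG1, all 44 among them, 485 up and 227 down. The edgeR count was 21 with a surrogate variable, 12 with the clock score, 2 (Nkd1 and Pnliprp1) with 6 libraries and 7 with replicate 3 as the 1 AEG1_MYC library. It was 29, 29 and 24 without WT replicate 1, 2 or 3, 4 (Gm106, Nkd1, Pnliprp1 and Tlr12), 5 and 23 without AEG1 replicate 1, 2 or 3, and 21 without MYC replicate 2. Without AEG1_MYC replicate 1, 2 or 3 it was 67, 25 and 630. Nkd1 and Pnliprp1 kept their calls in 12 of 12 such fits, AF357359, Abcc4, Myc and Rian in 10, Kif26b, Rhbg and Slc1a2 in 9, Slc22a12 in 7, Gucy1b3 and Sp5 in 4, Aacs, Amacr and Mirg in 2, and Socs3 in 1.

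Among the lists of AEG1_MYC versus AEG1, pericentral genes had the lowest adjusted p, 21 of 22 with a median of 1.71 (adjusted p = 9.1e-17, and adjusted p = 0.531 with an estimated correlation), with Sp5 (3.42 ± 0.54), Slc1a2 (3.49 ± 0.46), Rhbg (3.14 ± 0.43) and Nkd1 called over all genes. Cell cycle genes had a median of 1.46 (38 of 39 positive, adjusted p = 4.1e-13, and adjusted p = 0.690 with an estimated correlation), with the mitotic kinase Plk1 at 1.95 ± 0.49 and cyclin B2, Ccnb2, at 2.39 ± 0.60. Ribosomal proteins had a median of 0.49 (adjusted p = 7.4e-13, and adjusted p = 0.690 with an estimated correlation) and ribosome biogenesis genes 0.32 (adjusted p = 1.9e-04, and adjusted p = 0.855 with an estimated correlation). Imprinted transcripts had a median of 0.54 (adjusted p = 5.4e-05, and adjusted p = 0.486 with an estimated correlation). Acute phase genes had a median of 0.96 (adjusted p = 0.00634, and adjusted p = 0.855 with an estimated correlation), but -0.10 without AEG1_MYC replicate 1 (adjusted p = 0.965), the library with neutrophil markers at 4.33. Fetal liver genes had a median of 0.67 (adjusted p = 0.0296) and nucleotide synthesis 0.21 (0.0102), each with adjusted p = 0.708 with an estimated correlation.

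Lipogenesis genes were lower in AEG1_MYC than in AEG1, 19 of 25 with a median of -0.76 (adjusted p = 8.1e-05, and adjusted p = 0.708 with an estimated correlation), with Elovl6 at -1.91 ± 0.39, Fasn at -1.53 ± 0.37 and ATP citrate lyase, Acly, at -1.88 ± 0.51. The median was -0.23 without AEG1 replicate 3 (adjusted p = 0.0259) and -0.34 without AEG1_MYC replicate 2 (adjusted p = 0.00116). The mean log2 difference of these genes from WT was -0.01, 0.46 and 1.18 in AEG1 replicates 1, 2 and 3, and 0.40, -0.80 and -0.08 in those of AEG1_MYC. Endothelial markers had a median of -0.34 (adjusted p = 0.00121, and adjusted p = 0.690 with an estimated correlation), with Kdr at -0.60 ± 0.13, and stellate cell markers -0.39 (adjusted p = 0.0420, and adjusted p = 0.708 with an estimated correlation), with Reln at -1.21 ± 0.25 and, the other way, the collagen cross-linking Lox at 1.63 ± 0.45. Male-biased genes (median -0.84, adjusted p = 3.6e-05) and unfolded protein response genes (-0.44, 2.8e-04) were lower as groups, each with adjusted p = 0.708 with an estimated correlation. So were cholesterol synthesis (-0.40, adjusted p = 6.4e-04) and coagulation (-0.18, 0.0242), each with adjusted p = 0.788 with an estimated correlation. Periportal genes (-0.60, adjusted p = 0.00220) and oxidative phosphorylation (-0.09, 0.0178) were lower with adjusted p = 0.855 with an estimated correlation for each. Adjusted over the list alone, 26 ribosomal, 25 cell cycle, 19 pericentral, 11 acute phase, 8 imprinted, 5 fetal, 2 ribosome biogenesis, 2 nucleotide and 1 stellate gene were called up, 8 lipogenesis, 7 stellate and 5 endothelial genes down, and 0 members of the 6 remaining lists; over all genes 4 pericentral, 2 imprinted and 1 acute phase gene were.

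Without AEG1_MYC replicate 2 the periportal median was -0.05 and its call was lost (adjusted p = 0.699), as was that of coagulation (0.533). The stellate call was lost without AEG1 replicate 3 (0.262) or AEG1_MYC replicate 1 or 3 (0.345 and 0.0731), the fetal call without AEG1 replicate 1 or 2 (0.0748 and 0.0747) or AEG1_MYC replicate 1 (0.106), the oxidative phosphorylation call without AEG1 replicate 2 (0.0940) or AEG1_MYC replicate 1 (0.504), and the cholesterol call without AEG1 replicate 3 (0.236). Medians of lost calls were -0.06 for cholesterol and -0.17 for stellate genes without AEG1 replicate 3, -0.05 for oxidative phosphorylation without AEG1 replicate 2 and -0.05 for coagulation without AEG1_MYC replicate 2. Without AEG1_MYC replicate 1 they were 0.44 for fetal, -0.04 for oxidative phosphorylation and -0.20 for stellate genes. With the call kept, medians without AEG1_MYC replicate 2 were 0.97 for pericentral, 0.40 for fetal, 0.18 for ribosome biogenesis and -0.40 for male-biased genes, the last -0.48 without AEG1 replicate 1. Without AEG1_MYC replicate 3 they were 0.49 for ribosome biogenesis, 0.40 for nucleotide synthesis, -0.67 for unfolded protein response, -1.31 for male-biased and -1.14 for periportal genes, the last -0.91 without replicate 1. In the fit with replicate 3 as the 1 AEG1_MYC library, assumed to vary like the other groups, 7 of the 17 lists were called. Medians were then 1.13 for pericentral, 1.09 for cell cycle, 0.43 for ribosomal protein, 0.13 for imprinted, -0.75 for lipogenesis, -0.37 for cholesterol and -0.36 for endothelial genes. The male-biased call was lost there (median -0.04, adjusted p = 0.873).

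AEG1_MYC against MYC asked what AEG-1 added to c-Myc. Myc itself was 58.4 to 165 CPM in AEG1_MYC and 23.4 to 53.8 CPM in MYC libraries, without overlap, though it was not called. The comparison therefore cannot tell AEG-1 from a higher Myc level. Nkd1 rose by 3.91 ± 0.16 (adjusted p = 1.3e-06), Pnliprp1 by 6.54 ± 0.51 (adjusted p = 4.7e-04), Rian by 5.93 ± 0.61 (adjusted p = 0.00310) and Meg3 by 5.65 ± 0.84 (adjusted p = 0.0282). Slc22a12 rose by 9.03 ± 1.32 (adjusted p = 0.0254), Slc1a2 by 3.95 ± 0.47 (adjusted p = 0.0103), Abcc4 by 3.86 ± 0.49 (adjusted p = 0.0129) and Rhbg by 3.02 ± 0.43 (adjusted p = 0.0237). Mirg was called too (adjusted p = 0.0129), with 363 reads in AEG1_MYC and 3 in MYC. In all 28 genes were called, 28 up and 0 down in edgeR, with 2075 at an unadjusted p under 0.05, 863 of them lower, and no overlap in 2530 genes, 18.5%, where chance gives 10%. DESeq2 called 445, all 28 among them, 347 up and 98 down.

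That count was 6 with the clock score, 7 with 6 libraries alone and 3 (Gm106, Nkd1 and Pnliprp1) with replicate 3 as the 1 AEG1_MYC library. It was 17, 16 and 17 without WT replicate 1, 2 or 3, 16 and 18 without AEG1 replicate 1 or 2, 6, 7 and 6 without MYC replicate 1, 2 or 3, and 450 without AEG1_MYC replicate 3. Nkd1, Pnliprp1 and Rian kept their calls in 12 of 12 such fits, Abcc4, Mirg and Slc1a2 in 9, Rhbg in 5, Meg3 in 3 and Slc22a12 in 2.

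Pericentral genes had the lowest adjusted p among the lists of AEG1_MYC versus MYC, 21 of 22 with a median of 1.56 (adjusted p = 2.2e-20, and adjusted p = 0.486 with an estimated correlation). Cell cycle genes had a median of 0.94 (37 of 39 positive, adjusted p = 5.0e-08, and adjusted p = 0.708 with an estimated correlation), with thymidine kinase, Tk1, at 0.94 ± 0.24. Unfolded protein response genes had a median of -0.59 (21 of 26 negative, adjusted p = 7.9e-06, and adjusted p = 0.708 with an estimated correlation), with Manf at -1.40 ± 0.40 and, the other way, Trib3 at 1.76 ± 0.52. Periportal genes had a median of -0.66 (adjusted p = 7.3e-04, and adjusted p = 0.842 with an estimated correlation) and male-biased genes -0.63 (adjusted p = 6.5e-04, and adjusted p = 0.788 with an estimated correlation). Bile duct markers had a median of -0.66 (8 of 10 negative, adjusted p = 0.00847, and adjusted p = 0.695 with an estimated correlation), with the duct transcription factor Sox9 at -2.68 ± 0.80. Imprinted transcripts had a median of 0.36 (adjusted p = 0.00634, and adjusted p = 0.690 with an estimated correlation) and NRF2 targets 0.20 (adjusted p = 0.0282, and adjusted p = 0.770 with an estimated correlation), with Gstm2 at 2.40 ± 0.51. Interferon response (-0.45, adjusted p = 0.00121), acute phase (0.67, 0.0358) and oxidative phosphorylation (-0.08, 0.0282) each had adjusted p = 0.855 with an estimated correlation, and stellate markers (-0.29, 0.0402) had adjusted p = 0.708 with an estimated correlation. Adjusted over the list alone, 20 pericentral, 7 NRF2, 3 imprinted, 1 unfolded protein response and 1 acute phase gene were called up and 9 unfolded protein response genes and 1 NRF2 gene down, with 0 members of the 7 remaining lists; over all genes 3 pericentral, 3 imprinted and 1 NRF2 gene were.

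Without AEG1_MYC replicate 2 the calls of periportal (adjusted p = 0.404), male-biased (0.0700), bile duct (0.0513), imprinted (0.0761), interferon (0.0513) and NRF2 genes (0.0619) were lost. The acute phase median without AEG1_MYC replicate 1, where neutrophil markers stood at 4.33, was -0.18 (0.342), and the oxidative phosphorylation (0.553) and stellate (0.485) calls were lost there as well. The NRF2 (0.128), acute phase (0.205), bile duct (0.0748), interferon (0.0574) and oxidative phosphorylation (0.161) calls were lost without MYC replicate 3. NRF2 and stellate calls were also lost without AEG1 replicate 3 (0.0659 and 0.0510) or MYC replicate 1 (0.0651 and 0.0996), and the stellate call without AEG1_MYC replicate 3 (0.0798). Medians of lost calls were -0.15 for periportal, -0.15 for male-biased and 0.04 for imprinted genes without AEG1_MYC replicate 2, and -0.15 for stellate genes without replicate 1. Without MYC replicate 3 they were -0.04 for oxidative phosphorylation, -0.38 for bile duct and -0.32 for interferon genes. Acute phase genes had 0.69 and NRF2 targets 0.17 there, little changed from 0.67 and 0.20 with all libraries. Leaving out AEG1 replicate 3, which is outside the comparison, gave 0.20 for NRF2 targets and -0.28 for stellate genes. With the call kept, the cell cycle median was 0.54 and the stellate median -0.53 without AEG1_MYC replicate 2. Without replicate 3 medians were -1.04 for periportal, -1.22 for male-biased, -0.70 for interferon, 0.33 for NRF2 and -0.14 for oxidative phosphorylation genes. The NRF2 median was 0.31 without AEG1_MYC replicate 1 and 0.33 without MYC replicate 2, interferon -0.68 without MYC replicate 2 and male-biased genes -0.40 without MYC replicate 3. Where replicate 3 was the 1 AEG1_MYC library, assumed to vary like the other groups, 3 of the 12 lists were called, with medians of 1.07 for pericentral, 0.37 for cell cycle and -0.34 for unfolded protein response genes.

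The interaction asked how far livers with both transgenes departed from the sum of the single differences. Nkd1 was above that sum by 4.02 ± 0.21 (adjusted p = 2.0e-05), Tlr12, a Toll-like receptor, by 1.86 ± 0.21 (adjusted p = 0.0221) and the predicted gene Gm106 by 4.65 ± 0.60 (adjusted p = 0.0476). Nkd1 was 6.18, 5.72, 4.66 and 70.0 CPM in WT, AEG1, MYC and AEG1_MYC, Tlr12 was 15.0, 8.14, 11.7 and 23.0, and Gm106 was 0.298, 0.282, 0.296 and 7.34 CPM. Myc had an interaction of 1.16 ± 0.62 (adjusted p = 0.591), and Meg3 and Rian of 3.99 ± 1.03 (adjusted p = 0.360) and 4.34 ± 0.78 (adjusted p = 0.172). Mean Myc was 98.8 CPM in AEG1_MYC and 35.9 CPM in MYC livers, so a higher Myc level cannot be told apart from a joint action of the transgenes. In all 3 genes were called, 3 up and 0 down in edgeR, with 1266 at an unadjusted p under 0.05, 490 of them lower. DESeq2 called 146, 122 up and 24 down, and limma 5. Nkd1 kept its call in 12 of 12 fits without 1 library (adjusted p of at most 3.7e-04), and it was the 1 gene called without any WT or AEG1 replicate, MYC replicate 1 or AEG1_MYC replicate 2. Tlr12 kept it in 3 and Gm106 in 1. Leaving out MYC replicate 2 gave 2 genes, MYC replicate 3 also 2 (Nkd1 and Ces2c), and AEG1_MYC replicate 3 gave 32.

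Pericentral genes departed upwards as a group in the interaction, 21 of 22 with a median of 2.28 (adjusted p = 4.2e-23, and adjusted p = 0.486 with an estimated correlation), with Slc1a2 at 4.51 ± 0.62, Glul at 3.97 ± 0.88 and Sp5 at 3.75 ± 0.73. Cell cycle genes had a median of 1.06 (34 of 39 positive, adjusted p = 2.7e-06, and adjusted p = 0.708 with an estimated correlation). Departing downwards were unfolded protein response (median -0.53, adjusted p = 1.9e-04) and stellate genes (-0.47, 0.00798), each with adjusted p = 0.708 with an estimated correlation, and lipogenesis (-0.65, adjusted p = 0.00132, and adjusted p = 0.749 with an estimated correlation). Endothelial markers had a median of -0.32 (adjusted p = 7.2e-04, and adjusted p = 0.690 with an estimated correlation), with Kdr at -0.75 ± 0.19. Oxidative phosphorylation (-0.11, adjusted p = 0.00386), male-biased (-0.58, 0.00634) and periportal genes (-0.58, 0.0138) each had adjusted p = 0.855 with an estimated correlation. Bile duct markers (-0.44, adjusted p = 0.0296) and imprinted transcripts (0.30, 0.0360) each had adjusted p = 0.708 with an estimated correlation. The pancreatic acinar list, of which 2 genes were tested, had a median of 3.19 (adjusted p = 0.0102, and adjusted p = 0.531 with an estimated correlation), made by Pnliprp1 at 6.17 ± 1.02 with Cela1 at 0.20 ± 0.59. Adjusted over the list alone, 19 pericentral, 3 imprinted and 1 pancreatic gene were called up, and Kdr and the duct factor Onecut2 (-0.59 ± 0.17) down, with 0 members of the 7 remaining lists; over all genes Nkd1 was the 1 list member called.

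Of these 12 calls, the pancreatic one was lost without WT replicate 2 or 3, AEG1 replicate 2 or 3, MYC replicate 1 or 2, or AEG1_MYC replicate 1 or 3 (adjusted p = 0.0571 to 0.222), and the imprinted one without WT replicate 2, AEG1 replicate 2 or 3, MYC replicate 1, or AEG1_MYC replicate 1 or 2 (0.0652 to 0.284). The bile duct and periportal (each 0.0659), lipogenesis (0.103) and stellate (0.109) calls were also lost without AEG1 replicate 3. The bile duct median was then -0.53 and the periportal one -0.58, no smaller in size than with all libraries. Without AEG1_MYC replicate 2 the bile duct (0.113), male-biased (0.174) and periportal (0.802) calls were lost, and without replicate 1 the oxidative phosphorylation (0.174) and stellate (0.131) calls. The bile duct call was lost also without WT replicate 1 (0.137) or MYC replicate 3 (0.158), the male-biased call without MYC replicate 3 (0.0626) and the oxidative phosphorylation call without WT replicate 1 (0.0515). Medians without AEG1_MYC replicate 2 were -0.01 for periportal, -0.28 for male-biased and 0.16 for imprinted genes. Without AEG1 replicate 3 lipogenesis had -0.18, stellate genes -0.29 and imprinted transcripts 0.51. Imprinted transcripts had 0.14, 0.19 and 0.16 without WT replicate 2, AEG1 replicate 2 or MYC replicate 1, and without WT replicate 1 bile duct markers had -0.26 and oxidative phosphorylation -0.07. With the call kept, the cell cycle median was 0.64 without WT replicate 1, lipogenesis -0.39 without AEG1_MYC replicate 2, stellate markers -0.28 without MYC replicate 1 and oxidative phosphorylation -0.05 without AEG1 replicate 2. Without AEG1_MYC replicate 3 it was -0.98 for periportal, -1.33 for male-biased, -0.67 for bile duct and 0.45 for imprinted genes. Male-biased genes had -0.90 without WT replicate 3 and -0.38 without AEG1 replicate 1, bile duct markers -1.07 without WT replicate 3, and imprinted transcripts 0.48 without MYC replicate 3. The pancreatic median was 0.24, 0.55 and 0.76 without WT replicate 1, AEG1 replicate 1 or AEG1_MYC replicate 2. It turned to -0.43 without AEG1_MYC replicate 3 and to -0.09 without AEG1 replicate 3, and was 0.12 (without AEG1_MYC replicate 1) to 0.63 (without WT replicate 2) in the other fits that lost its call. When replicate 3 was the 1 AEG1_MYC library, assumed to vary like the other groups, 6 of the 12 lists were called. Medians were then 1.62 for pericentral, 0.75 for cell cycle, -0.50 for lipogenesis, -0.42 for endothelial, -0.52 for stellate and 0.85 for pancreatic genes.

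Across genes, which are not independent replicates, the fold changes of MYC versus WT and of AEG1_MYC versus AEG1 had a Pearson r of 0.142 and a Spearman rho of 0.0706 over 13684 genes, with the same sign in 51.6%. The r was -0.00488 without MYC replicate 3 and 0.241 without WT replicate 1. For AEG-1 on its own and on the MYC background, r was 0.0758, rho 0.0289 and the same sign in 50.6%, with r -0.121 without AEG1 replicate 3 and 0.215 without WT replicate 1. These pairs of comparisons share no library. As edgeR called 0 genes in each single-transgene comparison, overlaps of calls held 0 genes and were not tested. AEG1 versus WT and MYC versus WT share the WT libraries. Their r was 0.473 and the same sign was found in 66.8%, against a mean r of 0.512 (0.490 to 0.551) and 67.0% in 20 simulations of unchanged groups. The covariance was 0.0719, against 0.0609 on average and at most 0.0680 in those simulations, a difference of 0.0110 from their average. The simulated genes were drawn independently of each other, so the simulated range is likely too narrow to judge this difference. Leaving out 1 real library moved r between 0.359 and 0.621. Where the real WT libraries were kept, the simulated covariance was 0.0517 on average and the mean r was 0.473.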

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

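The settings with the clock score and without both AEG1_MYC replicates 1 and 2 were chosen only after the data were seen; the other tests in this part were chosen before their results were seen. Results are listed here because the effect of 1 transgene differed between the backgrounds without and with the other, by the interaction test. By genes these were Nkd1 (4.02), Gm106 (4.65) and Tlr12 (1.86, all log2). By lists, as median log2 values, they were pericentral genes (2.28), cell cycle (1.06), pancreatic acinar markers (3.19) and imprinted transcripts (0.30) upwards. Downwards they were unfolded protein response (-0.53), lipogenesis (-0.65), periportal genes (-0.58), oxidative phosphorylation (-0.11), male-biased genes (-0.58), endothelial markers (-0.32), stellate cell markers (-0.47) and bile duct markers (-0.44). With an estimated correlation camera called 0 of these 12 lists. The pancreatic median turned to -0.43 without AEG1_MYC replicate 3 and -0.09 without AEG1 replicate 3. Without AEG1_MYC replicate 2 the periportal median was -0.01 and the male-biased one -0.28, and without AEG1 replicate 3 the lipogenesis median was -0.18; these calls were then lost.

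For the interaction, 4 of 100 splits of the 12 libraries, the real one included, gave at least 3 called genes, a share under 0.05. The splits were drawn at random, so the share is itself uncertain. They shuffle all genotypes, so they bear on any difference between genotypes and not on the interaction alone. The highest other split gave 418 genes, which points to a structure of the samples; that split put AEG1_MYC replicates 1 and 2 and MYC replicate 3 in 1 group, and what made its calls was not tested. The interaction count was 1 (Nkd1) without AEG1_MYC replicate 2, and it was 1 as well without any WT or AEG1 replicate or MYC replicate 1.

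Pericentral genes were higher in AEG1_MYC than in WT by a median of 1.03 log2 (adjusted p = 2.3e-11, and adjusted p = 0.690 with an estimated correlation). Replicate 2 alone, where Glul stood at 15863 CPM, was argued against as the whole cause: without it the list was still called (adjusted p = 4.8e-10, median 0.65), and in replicate 3 alone, the 1 library left without replicates 1 and 2 and assumed to vary like the other groups, the median was 0.64. With the clock score as a covariate the median was 1.15 times its value without it (adjusted p = 3.7e-12), which argues against a linear effect of that score as the cause. The score was 3.91 to 7.29 in AEG1_MYC and -5.14 to 3.01 in WT libraries, without overlap. Its slope thus comes from the spread within genotypes, and the fit cannot decide on the time of collection itself. More pericentral tissue in the sampled piece was predicted to raise the broad genes of that zone too. The 6 broadly pericentral genes of this list, Cyp2e1 and Cyp1a2 among them, had a median of 0.64, 6 of 6 above 0. They ran from 0.05 (Cyp27a1) to 1.47 (Gulo). The SE of that median, 0.26, is taken over genes, not mice, and none of the 6 was called (adjusted p = 0.161 to 0.888). As the 6 are members of the list already called up, a median above 0 was likely beforehand. It can hardly tell more such tissue from higher expression in the same tissue. The periportal median was -0.65 with all libraries but -0.09 without AEG1_MYC replicate 2. The explanation by tissue stays open. So does an action of both transgenes on the Wnt target genes of this list, which was not tested apart from it.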

How the results depend on the processing

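Leaving out AEG1_MYC replicates 1 and 2 together, the clock score and the camera test on z-scores were chosen only after the data were seen. Called genes named in the text kept their direction and call in 656 of their alternatives and lost the call in 330, with 0 reversals. Called lists kept theirs in 1132, lost the call in 316 and reversed in 10. The results of Myc and Mtdh that were not called stayed so in 229 and became called in 3. Other uncalled genes were not counted here. Nkd1 and Pnliprp1 kept each of their calls under every alternative run. Scaling by RLE or upper quartile moved the median of all genes by less than 0.1 log2. No paired analysis was possible because replicate numbers were given in accession order and pair no mice. The sex covariate was not run, since Xist was at most 0.781 CPM in all 12 libraries. The cause of each change was not tested, except that fits on fewer libraries hold fewer degrees of freedom.

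DESeq2 called 15 genes in AEG1 versus WT, 28 in MYC versus WT, 653 in AEG1_MYC versus WT, 712 in AEG1_MYC versus AEG1, 445 in AEG1_MYC versus MYC and 146 in the interaction, where edgeR called 0, 0, 36, 44, 28 and 3. Limma with library weights, which gave AEG1_MYC replicate 2 a weight of 0.234, called 23 in AEG1_MYC versus WT and 5 in the interaction. A surrogate variable left 9 in AEG1_MYC versus WT, 21 in AEG1_MYC versus AEG1 and gave 8 in the interaction. The clock score gave 1 in MYC versus WT (Gtf2ird1) and left 12, 12 and 6 in AEG1_MYC versus WT, AEG1 and MYC, and 1 in the interaction. The 6 compared libraries alone left 2, 2 and 7 in those 3 comparisons. Without AEG1_MYC replicates 1 and 2, which leaves 1 library in that group, the counts were 4, 7 and 3, and 1 in the interaction, which had 5 without the robust step.

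Leaving out 1 library gave 0 to 1 genes in MYC versus WT (1, Myc, without AEG1_MYC replicate 2). AEG1_MYC versus WT gave 6 (without WT replicate 2) to 687, AEG1_MYC versus AEG1 4 (without AEG1 replicate 1) to 630, AEG1_MYC versus MYC 6 (without MYC replicate 1 or 3) to 450, and the interaction 1 to 32, each highest without AEG1_MYC replicate 3. Fry called 10 of the 240 list tests, 0 each in AEG1 versus WT and MYC versus WT. It called 3 each in AEG1_MYC versus WT and versus AEG1, and 2 each in AEG1_MYC versus MYC and the interaction. Of the 81 called by camera, an estimated correlation left 0; RLE gave 81, the clock score 91, z-scores 88, single left-out libraries 69 to 92, and 46 of the 81 were lost without at least 1 library. Across genes r ranged from -0.00488 (without MYC replicate 3) to 0.241 (without WT replicate 1) for MYC on both backgrounds and from -0.121 (without AEG1 replicate 3) to 0.215 (without WT replicate 1) for AEG-1. With the shared WT it ranged from 0.359 (without MYC replicate 1) to 0.621 (without WT replicate 3).

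Lists whose test turned direction without AEG1_MYC replicates 1 and 2, with their medians then, were ribosome biogenesis (-0.14 against WT, -0.11 against AEG1), acute phase genes (0.0173 against WT and -0.13 against MYC), oxidative phosphorylation (0.0126 against AEG1, 0.0427 against MYC) and male-biased genes (0.19 against MYC, 0.11 in the interaction). The acute phase test also turned against WT and MYC without AEG1_MYC replicate 1 alone. Over fits without 1 library its median ranged from 0.0383 without AEG1_MYC replicate 1 to 1.15 without replicate 3 against WT, and from -0.18 to 0.98 against MYC. Depth limits genes of few reads, such as Mirg with 3 reads in MYC livers.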

Other observations

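The tests on Xist and on the shares of Y-linked genes, the clock score and the fits without AEG1_MYC replicates 1 and 2 were chosen only after the results were seen. In 12 lists no comparison was called, and their medians ranged as follows over the 6 comparisons. Immune markers were among them: Kupffer cells and macrophages (0.02 to 0.42, lowest adjusted p = 0.455), T and NK cells (-0.77 to 0.33, 0.331) and neutrophils, of which 4 genes were tested (-1.14 to 4.81, 0.120). Liver transcription factors ranged from -0.10 to 0.09 (0.639), glycolysis from -0.05 to 0.07 (0.488), gluconeogenesis and glycogen from -0.10 to 0.12 (0.325), and PPARA targets and fatty acid oxidation from -0.14 to 0.07 (0.121). Xenobiotic cytochrome P450 and conjugation genes ranged from -0.15 to 0.25 (0.182), genes of epithelial-mesenchymal transition from 0.02 to 0.36 (0.275) and circadian genes from 0.14 to 0.88 (0.0842). Adipocyte markers (0.12 to 1.22, 0.282) and erythroid markers (-0.45 to 0.13, 0.331) had 2 tested genes each.

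Meg3, Rian, AF357359 and Mirg, each called in AEG1_MYC versus WT, lie in this order between Dlk1 and the end of Mirg. They are the tested genes placed in that stretch, and whether they are separate transcripts was not tested. In AEG1 versus WT, Meg3 stood at 1.66 ± 0.73 and Rian at 1.59 ± 0.55, with neither called (adjusted p = 0.9997 for each). In AEG1_MYC livers Meg3 was 349, 273 and 221 CPM and Rian 125, 70.2 and 72.2 CPM, so neither followed the larger departures of replicate 2. Pnliprp1, a gene of the pancreatic list, was 11.5, 26.1 and 15.5 CPM in those livers, while the other tested acinar gene, Cela1, was 17.5, 14.6 and 42.8 CPM there and 45.8 ± 10.9 CPM in WT. The liver tumour markers Afp and Gpc3 were 3.81 ± 0.917 and 1.32 ± 0.255 CPM in WT and 4.11 ± 2.22 and 0.908 ± 0.165 in AEG1_MYC, and neither was called (adjusted p = 0.910 and 0.520). They do not stand for their list of fetal liver and liver tumour genes, which had a median of 0.43 there (camera adjusted p = 0.0403). That call was lost in 8 of the fits without 1 library.

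Y-linked genes were low in AEG1_MYC replicate 2, at 3.21% (Ddx3y), 2.51% (Eif2s3y), 5.13% (Kdm5d) and 5.70% (Uty) of their mean in the other 11 libraries. A female or mixed-sex sample was argued against, as Xist there was 0.683 times its highest value elsewhere. The whole Y chromosome may be missing from most of the sampled cells, since the largest share left was 2.27 times the smallest. A cell clone with other chromosome-wide changes stays a candidate explanation: the largest autosomal shift was 0.305 log2 in size (-0.31 on chromosome 4, bootstrap SE 0.0169), against at most 0.0753 in the other 11 libraries, and 12 autosomes lay above that value. The pattern is in 1 mouse, and no group of the design bears on it.

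The 36 genes called in AEG1_MYC versus WT were set against the clock and against the acute-phase response of replicate 1. With the clock score their fold changes had a median ratio of 0.991 (0.850 to 1.07) to those without it and 36 of 36 kept their sign. That argues against a linear effect of the score as the source of the fold changes. As the score did not overlap between AEG1_MYC and WT libraries, the fit cannot decide on a time of collection as their source. Calls did fall, to 12 of 36, which met the other bound set for that explanation; the median SE went from 0.502 to 0.514 and adjusted p values reached 0.160 with a median of 0.106, so the calls are not described as kept. Without AEG1_MYC replicate 1 the median ratio was 1.01 and 22 of 36 were still called, so their fold changes did not rest on that library. The ratio was 0.91 without replicate 2 and 1.07 without replicate 3. As these genes were called over all 3 AEG1_MYC libraries, genes high in replicate 1 alone were unlikely to be among them. The test can therefore hardly decide on the acute-phase response as their source. The labels give no litter or batch, so neither was tested.

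Splits of 6 libraries into 3 and 3 were counted for each pair of genotypes, 10 splits each with the real one included, which are too few splits for a share under 0.05. In AEG1_MYC versus WT 1 of 10, the real one, gave as many genes as the real 36 (highest other 2), in AEG1_MYC versus AEG1 likewise 1 of 10 (44, highest other 2) and in AEG1_MYC versus MYC 1 of 10 (28, highest other 1). In AEG1 versus WT it was 10 of 10 (real 0, highest other 2) and in MYC versus WT 10 of 10 (real 0, highest other 0).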
